A study of Rattus norvegicus with 4 samples.

How the data were processed

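The deposited values are raw UMI counts per gene and nucleus, written as a matrix of whole numbers with 62845195 entries and 108629376 UMIs over 48637 barcodes and 32623 genes. Nuclei were isolated by Dounce homogenisation in a lysis buffer and libraries were made with a 10x 3' v3 kit and sequenced on a NovaSeq, per the labels' protocols. The matrix was made with cellranger 5.0.1, per the file headers, whereas Cell Ranger 6.1.1, Seurat (no version) and the build rn7 are listed, per the submitters' processing notes. The 2 versions differ, and 6776 gene symbols are contig names of the older assembly Rnor_6.0, per the deposited gene table, so the build behind the counts is not settled. Filters beyond the cell calling are not given in the sources used here. Of the 32623 features, 17236 had symbols also listed in the reference table of the assembly GRCr8, which was used for names only. No source ties the barcode suffixes 1 to 4 to the 4 samples.

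Choices made before the data were examined were the filters, the clustering, the marker genes of 18 classes, the 23 gene lists and the alternatives in the closing section, except the removal of cluster 8 and scrublet's automatic threshold as an alternative, both added later. Nuclei with at least 500 UMIs, 300 genes and at most 10% mitochondrially encoded UMIs were kept, 9013, 14603, 16453 and 6521 in libraries 1 to 4. Doublets were scored per library with the scrublet step of scanpy 1.11.5. Its automatic threshold, which had been planned, would have removed 978, 1, 6008 and 4 nuclei, so the highest scores were removed at 0.8% per 1000 nuclei instead, 650, 1706, 2166 and 340 nuclei. Counts were scaled to 10000 UMIs per nucleus and log-transformed, and genes seen in at least 10 nuclei were used, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 29 clusters without integration. Median mitochondrial shares were 0.0767, 0.481, 1.29 and 1.10% in libraries 1 to 4, and haemoglobin took 0.0194, 0.0693, 0.201 and 0.514% of UMIs.

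Clusters were named from the fixed markers by a rule set after the clusters were seen. At least 3 markers of a class had to be 2-fold higher than in clusters of other classes of the same libraries and seen in at least 5% of nuclei, and the mean marker log2 fold had to exceed that of the next class, closely related classes aside, by 0.5. That named 12 classes and left 3 clusters unnamed. Names end in "-like" because they rest on markers alone. Of the fixed symbols, 21 were not found under an older or newer name, among them 17 of the 363 list symbols, and are not analysed here.

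UMIs were summed over the nuclei of a class in a library and divided by the class total (CPM). Intervals of CPM are exact Poisson, of ratios conditional binomial and of shares Clopper-Pearson. The lists were ERR and PGC-1 regulators (the receptor network), fatty acid oxidation, TCA cycle, respiratory chain, glycolysis, hypoxia, sarcomere, calcium handling, stress remodelling, immediate early, heat shock, unfolded protein response, antioxidant and ferroptosis, cell death, autophagy, inflammatory, interferon, matrix, endothelial activation, endothelial quiescence, resident macrophage, recruited macrophage and cell cycle. A list value is the median over members, with at least 30 UMIs in the class, of log2(CPM + 10), either for a class minus all other named classes of the same library or for a library minus the mean of the 4 libraries. In the first kind class markers were left out, which left too few resident macrophage genes for a value. Percentiles come from 10000 random lists matched on expression in 20 bins, and intervals of list medians from 500 Poisson resamples.

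With no map from suffixes to samples the planned ratios against the sham sample could not be formed. Values by suffix, the contrasts between classes and the reference to the 4-library mean were chosen after the data were seen, in place of the planned shares of the pool alone. The genes named singly were replaced by a substitute rule written before their values were seen. It takes, in cardiomyocyte-like nuclei, the 10 widest spans between libraries and the 3 highest and 3 lowest genes of each library against the others, and in the other 3 classes the 8 widest spans. Genes needed 100 UMIs in the highest library, a gene symbol and at least 0.25 of the CPM of that library's highest class. Esrra, Esrrb, Esrrg, Ppargc1a, Ppargc1b, Ppara and Perm1 were always named, and examples are the 2 highest and 2 lowest members of a list. Some genes that these rules picked are not reported here. The free RNA share of a class is the share of its UMIs at which subtracting the profile of all nuclei of the library brings the summed markers of the other classes, closely related ones aside, to 0. It also takes in RNA of other cells inside a droplet, and so is an upper estimate of free RNA. Where free RNA was subtracted, counts that fell below 0 were set to 0.

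The list steps were tested on simulated data made from the cardiomyocyte-like class sums of 13692 genes. Simulated folds of 1.5, 2, 4 and 0.5 came back at log2 0.56, 0.96, 1.95 and -0.93 for genes of at least 100 CPM, and at 0.41, 0.72, 1.64 and -0.71 over all changed genes. Of 100 lists of unchanged genes 3% fell outside the 95% range, and of 50 lists of doubled genes 100% lay above the percentile 97.5. Counts were drawn as Poisson from 1 shared profile with library 1 altered, without free RNA. The simulation therefore covers list values between libraries, and percentiles of a class against the other classes were not simulated. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.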

Results

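Single-nucleus RNA sequencing was carried out on the infarct zone of Sprague Dawley rat hearts, with 1 library for each of 4 samples: 1 sham sample and 3 samples of myocardial infarction whose names carry 1, 6 and 24 h. The treatment labels call those hours reperfusion, whereas the series text describes ligations of 1, 6 and 24 h and, apart from them, reperfused hearts, so what the hours count is not settled here. The 4 libraries lie in 1 matrix of 32623 genes and 48637 barcodes, in which the barcode suffixes 1 to 4 separate the libraries but are not tied to the samples. No comparison with the sham sample or between times was therefore made, and the libraries are called 1 to 4 by suffix alone. Cell classes were compared with one another inside each library, and differences between libraries are given as values per library. After filtering, 8363, 12897, 14287 and 6181 nuclei were used from libraries 1 to 4, with medians of 1298, 603, 1883 and 2213 unique molecular identifiers (UMIs) per nucleus. With 1 library per group there is no replicate check and no p-value, and every interval is a 95% interval that covers counting error only.

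Fibroblast-like, endothelial-like, macrophage-like and cardiomyocyte-like nuclei were the 4 most numerous named classes, with 16.4, 15.5, 14.0 and 12.6% of the 41728 nuclei in the pool. Cardiomyocyte-like nuclei, named by contractile genes such as Ttn, Ryr2 and Tnnt2, made up 31.9% (30.9 to 32.9%) of library 1, 3.08% (2.79 to 3.39%) of library 2, 8.72% (8.26 to 9.20%) of library 3 and 15.6% (14.7 to 16.5%) of library 4. Macrophage-like nuclei made up 3.64, 2.64, 31.7 and 11.2%, and neutrophil-like nuclei 0.07, 0.55, 6.01 and 2.35%. Fibroblast-like nuclei made up 28.2, 5.76, 20.6 and 12.8%, endothelial-like nuclei 23.8, 1.06, 16.4 and 32.1%, and pericyte-like nuclei 8.13, 1.12, 2.93 and 5.32%. T or NK cell-like nuclei were 1.64% of the pool, lymphatic endothelial-like nuclei 1.01%, dendritic-like nuclei 0.95%, B cell-like nuclei 0.69%, Schwann or neuronal-like nuclei 0.58% and epicardial-like nuclei 0.12%. In library 2, 84.6% of nuclei lay in clusters that no marker set named, against 0.16, 5.34 and 14.2% in libraries 1, 3 and 4. Among them, unnamed cluster 9 held 1130 nuclei of library 2 and scored highest for endothelial markers without meeting the naming rule, so it is not in the 1.06%. Unnamed cluster 0, led by Cyba, Cd74 and Apoe, held 9777 nuclei of library 2 and scored highest for macrophage markers. Cluster 0 had 0 markers past the bounds of that rule, so it is not in the 2.64%. Among named nuclei only, the cardiomyocyte-like share was 32.0, 20.0, 9.21 and 18.2%, and the fibroblast-like share 28.2, 37.4, 21.7 and 14.9%. The macrophage-like share of named nuclei was 3.641, 17.13, 33.45 and 13.01%, and the neutrophil-like share 0.072, 3.577, 6.352 and 2.734%. Library 2 thus lay above library 4 for both, and not below it as among all nuclei. The endothelial-like share was 23.82, 6.902, 17.37 and 37.45%, and the pericyte-like share 8.144, 7.305, 3.098 and 6.204%. Depth differed between classes and libraries, with medians of 2596, 1978, 4720 and 5478 UMIs in cardiomyocyte-like nuclei and 949.5, 998, 1614 and 1759.5 in macrophage-like nuclei. The library 2 share of cardiomyocyte-like nuclei depended on the filter, at 13.6% when at least 1000 UMIs were asked of each nucleus, and the shares of libraries 3 and 4 were 4.01 and 7.55% without the cluster of highest UMI count.

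**Figure D1:**
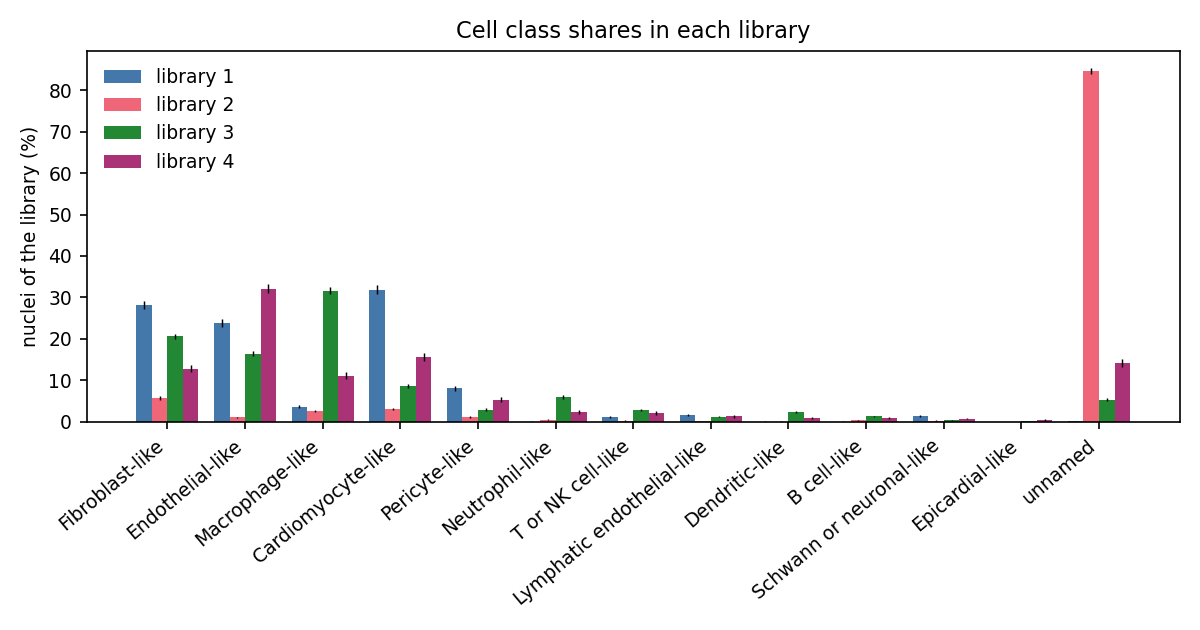
Share of each library's nuclei (%, y axis) in each named class and in unnamed clusters (x axis), with exact 95% counting intervals as bars. Cardiomyocyte-like nuclei took 31.9, 3.08, 8.72 and 15.6% of libraries 1 to 4, and unnamed clusters 84.6% of library 2.

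Of the 3 estrogen-related receptors, nuclear receptors that drive mitochondrial and fuel-use genes, Esrrg and Esrrb were enriched in cardiomyocyte-like nuclei of every library and Esrra much less so. Esrrg stood at 432, 339, 156 and 174 CPM (UMI counts of a gene scaled to the class total) in the cardiomyocyte-like nuclei of libraries 1 to 4, and at 77.0, 31.4, 13.5 and 9.63 CPM in all other named nuclei. That is 5.60-fold (5.13 to 6.13), 10.8-fold (8.51 to 13.8), 11.6-fold (10.3 to 13) and 18.1-fold (15 to 21.9) higher. Esrrb was scarcer, at 27.1, 27.2, 8.17 and 10.6 CPM in cardiomyocyte-like nuclei, and 28.5-fold (13.6 to 71.7), 18.6-fold (6.52 to 73.1), 40.3-fold (17.5 to 114) and 45.5-fold (14.9 to 226) above the other classes. Esrra was spread over classes, at 83.8, 145, 67.0 and 68.5 CPM in cardiomyocyte-like and 59.7, 174, 91.2 and 105 CPM in macrophage-like nuclei, and its cardiomyocyte excess over all other named nuclei was 3, 1.59, 1.14 and 1.27-fold.

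The coactivators and the lipid-sensing receptor that work with these receptors shared the cardiomyocyte bias. Ppargc1a, the coactivator PGC-1α, was 9.66, 11.6, 37.6 and 30-fold higher in cardiomyocyte-like nuclei than in the rest of libraries 1 to 4, from 622, 321, 162 and 205 CPM. Ppargc1b, its relative PGC-1β, was 5.85, 7.34, 3.89 and 5.34-fold higher, from 696, 697, 270 and 231 CPM. Ppara, a fatty acid-sensing receptor, was 10.2, 10.3, 16.2 and 20.0-fold higher, from 679, 282, 111 and 189 CPM, and Perm1, a muscle regulator induced by PGC-1, was 9.27, 4.66, 3.40 and 4.96-fold higher. Over the 11 fixed genes of this network, the median log2 difference between cardiomyocyte-like and other nuclei was 1.66, 1.08, 0.33 and 0.66, with 7 members higher in all 4 libraries and 4 lower. The lower ones included Nrf1, an activator of nuclear genes for respiration, at 43.0, 83.6, 114 and 91.5 against 160, 181, 147 and 131 CPM, and the corepressor Nrip1 at a median log2 of -0.34. At least 1 Esrrg UMI was seen in 63.2, 47.4, 50.4 and 52.2% of cardiomyocyte-like nuclei, against 4.02, 6.57, 1.53 and 1.66% of endothelial-like nuclei at medians of 1019, 1961, 1872 and 2505.5 UMIs and 11.9, 5.79, 6.56 and 6.57% of fibroblast-like nuclei. With 1000 UMIs drawn from each, the cardiomyocyte-like shares were 32.3, 27.6, 17.5 and 17.9%. Free RNA was estimated at 27.7, 47.1, 70.7 and 73.7% of cardiomyocyte-like UMIs, and subtracting it raised the network's median of the 4 libraries from 0.87 (0.63 to 1.10) to 1.60, while a pseudocount of 1 CPM gave 1.90.

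**Figure D2:**
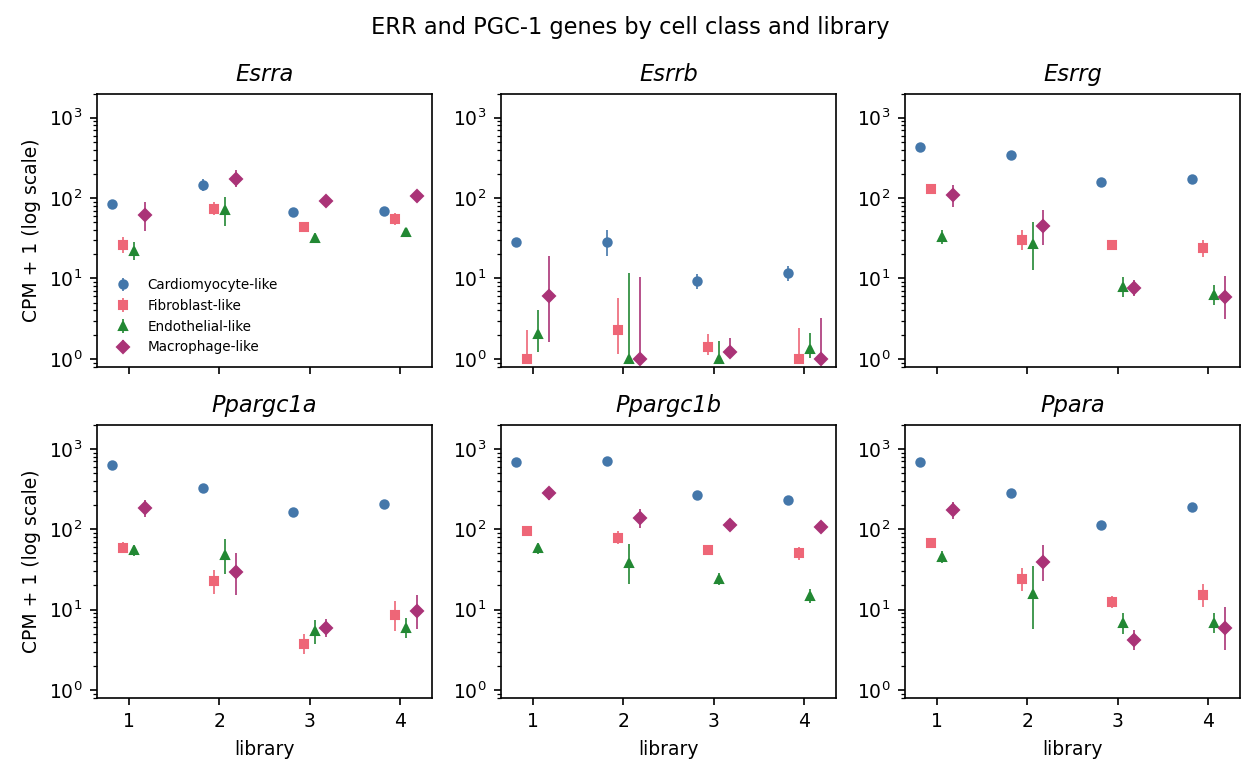
Level of 6 genes of the receptor network (CPM + 1, log scale, y axis) in 4 cell classes of each library (x axis), with exact 95% counting intervals as bars. Esrrg stood at 432, 339, 156 and 174 CPM in cardiomyocyte-like nuclei and Esrra at 59.7, 174, 91.2 and 105 CPM in macrophage-like nuclei.

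Fatty acid oxidation and the tricarboxylic acid (TCA) cycle lay above the other classes in cardiomyocyte-like nuclei of all 4 libraries, and the respiratory chain and glycolysis most clearly in library 1. The median of all 15959 genes was itself shifted by -0.28, -0.22, -0.10 and -0.11 log2 in cardiomyocyte-like nuclei of libraries 1 to 4, and list medians here are given relative to it. Counts of members higher or lower in all 4 libraries were taken before that shift, here and for the other classes. Fatty acid oxidation lay 0.95 log2 higher as the median of the 4 libraries, with 17 of 20 measured members higher in all 4 and none lower in all 4. Acsl1, which activates fatty acids, stood at 669, 385, 170 and 200 CPM against 74.1, 69.7, 51.0 and 44.6 CPM, and Pdk4, which turns the cell from glucose to fat, at 97.7, 53.5, 26.0 and 57.8 against 8.27, 6.21, 2.74 and 5.67 CPM. The TCA cycle lay at 1.04, 0.82, 0.28 and 0.37, with 15 of 18 members higher in all 4 libraries, among them Dlat of pyruvate dehydrogenase at a median log2 of 1.12. The nuclear-encoded respiratory chain lay at 0.82, 0.38, -0.07 and -0.09 in libraries 1 to 4, with 5 of 23 members higher and 2 lower in all 4, Ndufs1 of complex I at 0.75 and the ATP synthase subunit Atp5mc3 at -0.30. Glycolysis lay at 0.63, 0.17, 0.03 and 0.03, with 5 of 19 members higher in all 4 libraries. Pfkm, the muscle phosphofructokinase, stood at 156, 115, 49.9 and 59.2 against 30.9, 28.5, 19.4 and 21.8 CPM, and Ldhb, the heart lactate dehydrogenase, at 1.19 log2, whereas Slc16a3, a lactate exporter, was lower in all 4 at -0.51. Fatty acid oxidation and TCA cycle medians exceeded at least 99.9% of 10000 random lists matched on expression in each library.

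Calcium handling and contraction showed the widest gaps to the other classes. Calcium handling and ion channel genes lay 2.82 log2 higher with all 14 measured members higher in all 4 libraries, among them the release-unit protein Trdn at 1233, 559, 716 and 1208 CPM against 108, 58.4, 22.3 and 29.5 CPM. Of the sarcomere list, 6 genes had not served as class markers, and all 6 were higher in all 4 libraries, with Myom2 at 3.59. The stress remodelling list lay 1.43 higher, with 13 of 17 members higher in all 4 libraries. Xirp2, a protein of the intercalated disc, stood at 324, 2293, 2207 and 3308 CPM against 25.1, 361, 267 and 295 CPM, and Enah, an actin regulator, at 2.87 log2, while Runx1 was lower in all 4 at -1.15. Hypoxia genes were mixed, with 4 of 19 higher and 10 lower in all 4 libraries, and Vegfa, the vessel growth factor, stood at 3736, 2882, 273 and 447 against 444, 1127, 54.8 and 78.7 CPM, whereas Ndrg1 lay at -0.92.

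Inflammatory, interferon, matrix, cell death and recruited macrophage lists were lower in the cardiomyocyte-like nuclei than in the other classes of all 4 libraries, while heat shock and antioxidant lists varied. Member counts here were taken before the shift of all genes, which was itself -0.28, -0.22, -0.10 and -0.11 in this class and so favours lower members. No share of all genes lower in all 4 libraries stands beside them. Medians are relative to all genes. The 4-library median was -0.21 for immediate early genes (14 of 21 lower in all 4 libraries), -0.21 for cell death (18 of 22, at percentiles 26.2 and 38.4 of random lists for these 2 in library 2), -0.39 for inflammatory genes (18 of 20) and -0.46 for interferon genes (18 of 19). Matrix genes lay at -1.41, -0.84, -0.37 and -0.10, at percentile 20.8 of random lists in library 4, with 14 of 18 lower in all 4. The interleukin-1 receptor Il1r1 lay at -1.61, the initiator caspase Casp8 at -0.90, the interferon-induced Ifi27 at 9.22, 29.2, 126 and 195 against 124, 108, 197 and 378 CPM, and the collagen Col5a1 at -1.27. Unfolded protein response genes lay at -0.26 with 8 of 11 lower in all 4 before the shift. Antioxidant and ferroptosis genes lay at -0.21 with 10 of 15 lower before the shift, though at 0.09 in library 1 after it. Autophagy genes lay at -0.06 with 7 of 13 lower in all 4. Heat shock genes lay at 0.27, -0.08, -0.25 and -0.15 in libraries 1 to 4, with 5 of 10. Single members went the other way, with the chaperone partner Bag3 at 219, 158, 137 and 135 against 53.6, 83.6, 84.1 and 78.4 CPM, and the autophagy receptor Optn at 1.5 log2. Endothelial activation lay at -0.55, endothelial quiescence at -0.46 (near 0 in library 2), recruited macrophage genes at -0.64 and cell cycle genes at -0.22, with 8 of 9, 3 of 4, 9 of 9 and 4 of 4 members lower in all 4 libraries. The cell cycle list lay at -0.005 in library 1, at percentile 71.1 of random lists. The autophagy difference of -0.25 before the shift became 0.06 under median-of-ratios scaling.

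Between libraries, the widest list spans in cardiomyocyte-like nuclei were those of other cell types' genes, with recruited macrophage genes at -2.26, 0.39, 1.42 and 0.69 log2 and matrix genes at -2.03, 0.33, 0.95 and 0.65. Receptor network, fuel, contractile and stress genes also stood at different levels, though not all by wide spans. Among spans of matched random lists, the receptor network lay at percentile 94.0, fatty acid oxidation at 69.9, the respiratory chain at 63.7 and the TCA cycle at 1.75. Glycolysis lay at 99.2, the sarcomere list at 99.85, calcium handling at 99.91 and stress remodelling at 99.99. By level, fatty acid oxidation lay at percentile 100 in library 1 and 0.01 in library 3. Relative to the median of all genes and to the mean of the 4 libraries, the receptor network list lay at 0.77, 0.16, -0.71 and -0.52 log2 in libraries 1 to 4, fatty acid oxidation at 0.70, -0.02, -0.40 and -0.09, and the TCA cycle at 0.38, -0.03, -0.20 and -0.19. Before the median of all genes was taken off, the TCA cycle was nearly level, at 0.07, -0.03, -0.05 and -0.04. Calcium handling lay at 1.04, 0.18, -0.73 and -0.51, and the sarcomere list at 1.05, 0.39, -0.82 and -0.62, with Myh6, the fast myosin heavy chain, at 6467, 4227, 942 and 723 CPM. Stress remodelling lay at -0.89, 0.52, 0.30 and 0.38, with the natriuretic peptide Nppa at 14.6, 343, 521 and 417 CPM and Actn1 at 22.2, 576, 528 and 566 CPM. Glycolysis lay at -0.48, 0.40, -0.13 and -0.18, heat shock at -0.86, 0.06, 0.57 and 0.32, and immediate early genes at -0.75, 0.36, 0.10 and 0.15, with the small heat shock protein Hspb1 at 9.82, 155, 279 and 216 CPM. Autophagy lay at 0.10, -0.04, 0.07 and 0.01, and the respiratory chain at -0.01, -0.16, 0.10 and 0.09. The median of all genes in this class stood at -0.31, -0.01, 0.15 and 0.14.

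The cardiomyocyte-like values came from clusters 4 and 28 in library 1, cluster 22 in library 2 and clusters 8 and 12 in libraries 3 and 4. Cluster 8, with a median of 7042 UMIs, held 701 nuclei of library 3 and 537 of library 4 and carried 114 CPM of Esrrg in both. It also carried genes that stood highest in other classes, with Spp1 at 2884 and 1226 CPM and Vim at 1255 and 891 CPM there. Without cluster 8, the free RNA share of the class was 41.9% in library 3 and 32.1% in library 4, against 70.7 and 73.7% with it. In the nuclei left, Esrrg stood at 431, 340, 293 and 317 CPM, Ppargc1a at 622, 324, 286 and 374 CPM, and the receptor network list at 0.33, 0.05, -0.27 and -0.09. Esrrb then stood at 27.1, 28.8, 20.1 and 23.7 CPM, Ppargc1b at 696, 705, 473 and 391 CPM, and Ppara at 680, 287, 219 and 359 CPM. Calcium handling then lay at 0.51, -0.30, -0.23 and -0.02, the sarcomere list at 0.56, -0.07, -0.21 and -0.18, and stress remodelling at -1.35, 0.09, 0.67 and 0.57. Recruited macrophage genes lay at -2.251, 0.417, 1.595 and 0.409 and matrix genes at -1.682, 0.905, 0.918 and 0.303. For matrix genes library 2 then lay above library 4, and for recruited macrophage genes these libraries were about level. Fatty acid oxidation lay at 0.41, -0.36, -0.09 and 0.09 without cluster 8, and the TCA cycle at 0.22, -0.26, -0.02 and 0.04. Immediate early genes turned to -0.04 and -0.03 in libraries 3 and 4, glycolysis to 0.06 in library 3, heat shock to -0.09 in library 2 and autophagy to -0.06 in library 4. The respiratory chain lay at -0.03, -0.33, 0.29 and 0.12. With free RNA subtracted, Esrrg stood at 485, 545, 416 and 455 CPM, so its order among the libraries depended on the treatment of mixed RNA. Before the shift of all genes was taken off, library 1 lay above library 3 by 1.03 log2 for the receptor network and 0.64 for fatty acid oxidation, and these gaps were 0.31 and 0.20 without cluster 8, or 1.65 and 1.47 under median-of-ratios scaling. The respiratory chain, 0.56 higher in library 3 than in library 1, lay at -0.28 under that scaling.

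**Figure D3:**
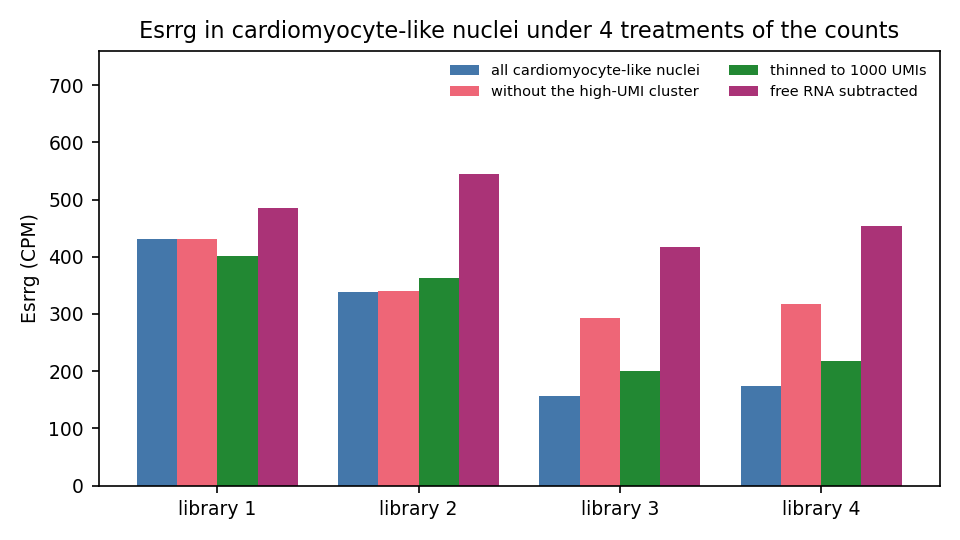
Esrrg level (CPM, y axis) in the cardiomyocyte-like nuclei of each library (x axis) under 4 treatments of the counts. The values of libraries 1 to 4 were 432, 339, 156 and 174 CPM with all nuclei and 485, 545, 416 and 455 CPM with free RNA subtracted.

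The genes with the widest span between libraries in cardiomyocyte-like nuclei each stood highest in another class of every library. Spp1 stood at 5.87, 1431, 2687 and 1022 CPM there and at 326, 7177, 8180 and 6529 CPM in macrophage-like nuclei, and Fn1, fibronectin, at 3.11, 467, 1126 and 535 CPM. Vim stood at 10.1, 228, 1161 and 736 CPM, and S100a6 at 4.91, 103, 770 and 414. Timp1 stood at 2.40, 84.6, 516 and 380, Tmsb4x at 34.1, 385, 1598 and 1572, S100a4 at 1.56, 77.8, 377 and 156, and Col1a1 at 16, 325, 856 and 563. Gpnmb stood at 2.51, 120, 634 and 198 CPM. Without cluster 8 all of these genes were lower in libraries 3 and 4, with Spp1 at 2033 and 533 CPM and Fn1 at 733 and 268. Vim then stood at 847 and 365 there, Col1a1 at 427 and 182, S100a6 at 513 and 228, and Timp1 at 406 and 215. Tmsb4x stood at 1101 and 775, S100a4 at 279 and 86.0, and Gpnmb at 368 and 90.1. With free RNA subtracted and counts below 0 set to 0, the library 3 excess over library 1 was gone. The log2 ratios of CPM + 10 went from 7.41 to -0.04 for Spp1 and from 5.41 to -0.14 for Timp1. Ratios this close to 0 can stand for almost no counts left, and are not read as reversed differences.

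Hs3st5, Coro6, Prodh1, Fbxw10, Lrrtm3 and Samd12 also differed between libraries and stood highest in the cardiomyocyte-like class of all 4. Hs3st5, a heparan sulfate sulfotransferase, stood at 597, 98.2, 55.9 and 63.2 CPM, Coro6, an actin-binding coronin, at 590, 254, 58.6 and 119, Prodh1, proline dehydrogenase, at 441, 110, 41.5 and 83.7, and Fbxw10 at 81.7, 2.92, 4.02 and 3.63. The synaptic adhesion gene Lrrtm3 stood at 132, 15.6, 195 and 423 CPM and Samd12 at 193, 161, 120 and 79.0. Tecr, an enzyme of fatty acid elongation, stood at 131, 34.0, 127 and 188, and the synapsin Syn3 at 22.2, 21.4, 73.8 and 222. Sycp3, a meiotic chromosome protein, had 0 UMIs in library 2 against 62.9 CPM in library 4, at least 21.6-fold higher against a floor of 3 UMIs. Ddx39b, an RNA helicase, stood at 269, 1442, 366 and 384 CPM, RT1-A2, a class I histocompatibility gene, at 2.88, 115, 22.0 and 22.8, and Mir3546 at 30.1, 208, 11.8 and 11.5. Ankrd9 stood at 104, 13.6, 7.29 and 9.68. It was nominally highest in dendritic-like nuclei of library 3, at 7.67 CPM, inside the cardiomyocyte-like interval of 5.54 to 9.43. In library 4 it was highest in B cell-like nuclei, at 23.5 CPM in a class of only 53 nuclei. Sntb1 stood at 493, 376, 223 and 163, and Fmn1 at 192, 43.7, 47.5 and 29.2. Dach1, Tmem63c and Smpd3 were highest in other classes, at 50.3, 104, 185 and 496, at 0.36, 5.83, 5.53 and 29.5, and at 1.2, 2.92, 58.6 and 15.7 CPM in cardiomyocyte-like nuclei. Without cluster 8 Dach1 stood at 47.7, 77.1, 54.3 and 69.5, Tmem63c at 0.54 and 2.06 in libraries 3 and 4, and Smpd3 there at 13 and 5.66. Samd12 then stood at 194, 169, 213 and 129, so that library 3 was the highest, and in libraries 3 and 4 Lrrtm3 stood at 381 and 767, Hs3st5 at 117 in both, Coro6 at 118 and 222, Prodh1 at 72.8 and 153, Tecr at 213 and 309, and Syn3 at 128 and 364. Sycp3 stood at 58.1 and 106, Sntb1 at 369 and 255, Ankrd9 at 11.4 and 14.9, Mir3546 at 19.6 and 19.0, and Fbxw10 at 7.06 and 5.15 there, with RT1-A2 at 14.4 in library 4.

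Fibroblast-like nuclei were set apart by matrix genes and, outside library 1, by cell cycle genes. The matrix and activated fibroblast list lay 0.72 log2 above the other classes relative to all genes, with 15 of 18 members higher in all 4 libraries and values above at least 99.9% of random lists. Col5a1, a fibrillar collagen, stood at 529, 686, 448 and 483 against 29.9, 108, 89.1 and 92.3 CPM, and Postn, a matrix protein of activated fibroblasts, at 197, 428, 889 and 882 against 9.17, 115, 296 and 205 CPM. Cell cycle genes outside the class markers lay at 0.12, 0.91, 1.10 and 0.81, at percentile 50.2 of random lists in library 1, with 4 of 4 higher in all libraries, Cdk1 at 3.50, 62.1, 75.3 and 46.4 against 1.24, 21.5, 25.1 and 17.5 CPM. Fatty acid oxidation lay at -0.39 with 16 of 20 members lower in all 4 libraries, and the receptor network at -0.55 with 7 of 11. The other classes include cardiomyocyte-like nuclei, which stood high for both lists, so these low values may mirror that class. No reference without it was formed. Unfolded protein response genes lay 0.20 higher, at percentile 44.9 in library 2, with 1 of 11 lower in all 4 and 5 higher, the chaperones Hspa5 at 0.51 and Hsp90b1 at 0.55 among these. Between libraries, the matrix list lay at -1.22, 0.46, 0.47 and 0.36, and Ltbp2, a matrix protein of the elastic fibre, stood at 29.1, 996, 443 and 642 CPM. Timp1, an inhibitor of matrix proteases highest in neutrophil-like or B cell-like nuclei of libraries 3 and 4, stood at 15.4, 261, 949 and 812 CPM. Slc37a2, a sugar phosphate exchanger highest in macrophage-like nuclei of libraries 1, 3 and 4, stood at 3.15, 280, 54.8 and 29.9. Hspa1b, an inducible heat shock protein, stood at 269, 10.3 and 10.6 CPM in libraries 2 to 4, with 0 UMIs in library 1, so that library 2 was at least 256-fold higher against a floor of 3 UMIs. Lyz2, Spp1, Gpnmb and S100a4, all highest in immune classes or nerve-associated nuclei, also spanned widely here, at 11.2 and 630, 20.3 and 2527, 14.0 and 510, and 13.6 and 488 CPM in libraries 1 and 3. These nuclei came from clusters 3 and 11 in libraries 3 and 4, 5 in library 1 and 16 in library 2. Free RNA was put at 17.5, 43.7, 44.7 and 38.3%.

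Endothelial-like nuclei carried adhesion and interferon genes at higher levels than the other classes. Endothelial activation genes outside the markers lay 1.19 log2 above the other classes with 7 of 9 higher in all 4 libraries. Selp, the leukocyte-capturing P-selectin, stood at 28.4, 168, 113 and 173 against 0.08, 16.4, 11.1 and 23.3 CPM, and the adhesion molecule Vcam1 at 85.4, 46.3, 117 and 96.9 against 2.73, 16.1, 14.6 and 13.8 CPM. The quiescence list lay at 1.97, 0.23, 1.10 and 1.22, with 2 of 4 measured members higher in all 4 libraries. Of these, the nitric oxide synthase Nos3 stood at 624, 636, 472 and 658 against 20.1, 150, 43.8 and 124 CPM, while Angpt1, a vessel-stabilizing ligand, was lower in all 4 at -1.79. Interferon genes lay 0.61 higher, with 10 of 19 members higher in all 4 libraries, led by Ifi27 at 202, 136, 410 and 525 against 31.6, 81.5, 142 and 211 CPM and Mx2, an antiviral GTPase, at 1.19 log2. Cell death genes lay at 0.52, 0.06, 0.15 and 0.28, at percentile 60 in library 2, with 8 of 22 higher and 3 lower in all 4, the inflammatory caspase Casp4 at 0.85, whereas Nlrp3 lay at -1. Fatty acid oxidation lay at -0.55 with 14 of 20 members lower in all 4 libraries, though at -0.10 and percentile 16.9 in library 3. This may again mirror the cardiomyocyte-like nuclei among the other classes. Between libraries, activation genes lay at -0.58, 0.27, 0.17 and 0.27. Reg3g, a secreted C-type lectin highest in this class, stood at 165, 545 and 335 CPM in libraries 2 to 4 against 0.69 CPM, from 2 UMIs, in library 1, a library 3 to library 1 ratio of 789 (218 to 6516). Timp1, Spp1, Lyz2, S100a4, S100a6 and Gpnmb, highest in other classes, spanned 4.15 to 633, 15.2 to 2997, 10.7 to 853, 2.42 to 375, 16.2 to 734 and 9.68 to 537 CPM. These nuclei came from clusters 6 and 26 in library 1, mostly cluster 13 in library 2, which gave 137 nuclei, and clusters 2 and 13 in libraries 3 and 4. Clusters 13 and 26 were led by genes such as Nrg1, Hmcn1 and Npr3, and clusters 2 and 6 by genes such as Meox2, Thsd7a and Ptprb. Cluster 13 gave 109 nuclei of library 2 and 0 of library 1, and cluster 6 gave 1846 of library 1. Differences between libraries in this class, and in Reg3g, a top gene of cluster 13, therefore also carry a different mix of clusters. The free RNA share was 20.2, 42.3, 58.5 and 43.2%.

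Macrophage-like nuclei carried genes of recruited macrophages and, less evenly, of glucose use and iron or oxidant defence. Recruited macrophage genes outside the markers lay 1.03 log2 above the other classes, with 8 of 9 higher in all 4 libraries. Gpnmb, a glycoprotein of lipid-handling macrophages, stood at 224, 981, 1968 and 1427 against 6.79, 166, 619 and 176 CPM, and Spp1, osteopontin, at 326, 7177, 8180 and 6529 against 12.0, 1784, 2991 and 967 CPM. Glycolysis lay at 0.13, 0.30, 0.37 and 0.49, at percentile 39.3 of random lists in library 1, with 9 of 19 members higher in all 4 libraries and 5 lower, the glucose transporter Slc2a1 at 14.9, 105, 90.1 and 77.9 against 7.70, 57.5, 45.6 and 34.2 CPM. Antioxidant and ferroptosis genes lay 0.33 higher with 8 of 15, at percentiles 89.5 to 99.8, Hmox1, which degrades haem, at 49.8, 135, 207 and 154 against 3.20, 48.0, 78.6 and 37.0 CPM. Cell death genes lay at 0.49, 0.47, 0.21 and 0.15, at percentile 88.1 in library 4, with 12 of 22 higher in all 4, Nlrp3, an inflammasome sensor, at 139, 89.4, 96.2 and 98.7 against 2.35, 21.9, 33.6 and 15.8 CPM, and its adaptor Pycard at 1.14 log2. Inflammatory genes lay at 0.28, 0.34, 0.05 and 0.24, at percentile 78.1 in library 3, with 9 of 20 members higher and 5 lower in all 4 libraries, Il1rn at 1.26 and Osmr at -1.27. Fatty acid oxidation lay at -0.26 with 13 of 20 members lower in all 4, which may also mirror the cardiomyocyte-like nuclei among the other classes.

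Between libraries, recruited and resident macrophage genes did not run in parallel in these nuclei. Recruited macrophage genes lay at -2.06, 0.30, 1.06 and 0.67, and resident macrophage genes at 0.86, -0.71, 0.12 and -0.01, with Cd163, a scavenger receptor of resident macrophages, at 573, 38.3, 173 and 220 CPM and Mrc1 at 1008, 286, 695 and 654 CPM. Library 3 lay 3.19 log2 above library 1 for recruited genes before the shift of all genes. The span was 3.02 to 3.23 over the alternatives run for this class, which were median-of-ratios scaling, the mean over nuclei and free RNA subtracted. None of these changed the filter, the doublet calls or the clusters. Timp1 stood at 12.4, 217, 757 and 436, Col1a1 at 17.4, 473, 738 and 376, and Ltbp2 at 2.49, 304, 68.1 and 64.4, with 1 UMI of Ltbp2 in library 1. Rbm20 at 1623, 416, 32.8 and 33.1 CPM, Fhod3 at 899, 294, 28.0 and 33.1 CPM and Vegfa at 1016, 1019, 31.5 and 61.3 CPM were higher in the cardiomyocyte-like nuclei of each library. Rbm20 stood there at 6061, 4379, 1338 and 1490 CPM. Libraries 1 and 2 gave 304 and 340 of these nuclei, mostly from cluster 19, and libraries 3 and 4 gave 4524 and 690, mostly from clusters 1 and 17. Free RNA was estimated at 52.3, 57.4, 55.5 and 52.8%.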

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

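No value was tested, since each group has 1 library and no suffix is tied to a group. No paired analysis was possible because no replicate numbers pair the samples, and leaving out a replicate was not possible with 1 library per group. The removal of cardiomyocyte-like cluster 8, which has the highest median UMI count, was among the tests chosen only after the result was seen. Scrublet's automatic threshold, the planned step, was replaced once its calls were seen and only then made an alternative, and the other alternatives were planned. A sign was counted as turned only where the interval of the first value excluded 0, and the cause was not tested. Of the values recomputed under alternatives, 86 of the receptor network genes stayed within their counting interval and 74 moved beyond it. For cardiomyocyte-like lists 200 stayed, 287 moved and 8 turned sign, for the named genes reported here 133, 215 and 2, and for lists of the other classes 239, 160 and 6, while 33 class shares stayed and 63 moved. In the values below, L1 to L4 are the libraries, share is the percentage of cardiomyocyte-like nuclei, list values are log2 gaps between 2 libraries, and Esrrg is in CPM in cardiomyocyte-like nuclei.

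List values here are on the scale before the shift of all genes was taken off, which differs from that of most list values in the results. On it they were 1.03 for the receptor network and 0.64 for fatty acid oxidation (both L1 minus L3), 0.12 for the TCA cycle (L1 minus L3), 0.56 for the respiratory chain (L3 minus L1), 1.71 for stress remodelling (L4 minus L1), and 0.87 and 0.78 for the receptor network and fatty acid oxidation against the other classes.

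Without a further filter, median UMIs were 1205, 610, 2045 and 2082, the share was 28.4% in L1, 6.68% in L3 and 10.9% in L4, the receptor network gap 0.71, fatty acid oxidation 0.43 and stress remodelling 1.89, Esrrg 225 in L3 and 236 in L4, and fatty acid oxidation against other classes 0.88. With the stricter filter the share was 46.1% in L1, 13.6% in L2 and 14.6% in L4, stress remodelling 1.83, and Esrrg 165 in L3 and 225 in L4. With doublets kept, the share was 35.1% in L1, 2.77% in L2 and 13.5% in L4, fatty acid oxidation 0.57, and Esrrg 406 in L1 and 206 in L4. With scrublet's automatic threshold, the share was 2.76% in L2, 4.38% in L3 and 13.3% in L4, the receptor network gap 0.40, fatty acid oxidation 0.24, the TCA cycle -0.0225 and the respiratory chain 0.47, Esrrg 320 in L3 and 207 in L4, and fatty acid oxidation against other classes 0.89. With principal components centred per library, the share was 4.75% in L2, 8.11% in L3 and 12.6% in L4, and Esrrg 177 in L2, 168 in L3 and 211 in L4.

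Without cluster 8, the share was 4.01% in L3 and 7.55% in L4, the receptor network gap 0.31, fatty acid oxidation 0.20, the TCA cycle -0.0532 and stress remodelling 2.21, Esrrg 293 in L3 and 317 in L4, and fatty acid oxidation against other classes 1.06. With median-of-ratios scaling, the receptor network gap was 1.65, fatty acid oxidation 1.47, the respiratory chain -0.28, stress remodelling 0.95 and autophagy (L3 minus L1) -0.31 against 0.42 on that scale, the fibroblast-like matrix list (L3 minus L1) 1.65 against 1.84, Esrrg 679 in L1, 129 in L3 and 144 in L4, and against other classes fatty acid oxidation 1.05 and autophagy 0.0561 against -0.25. With the mean over nuclei of each nucleus's own CPM, the receptor network gap was 0.75, the respiratory chain 0.51, stress remodelling 1.87 and macrophage-like fatty acid oxidation (L1 minus L2) -0.0864 against 0.29, and Esrrg 415 in L1, 198 in L3 and 209 in L4. With a pseudocount of 1 CPM, the receptor network gap was 1.35, fatty acid oxidation 0.71 and stress remodelling 1.94, and against other classes 1.90 for the receptor network and 0.98 for fatty acid oxidation. With nuclei thinned to 1000 UMIs, Esrrg was 401 in L1, 201 in L3 and 217 in L4.

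With free RNA subtracted, the receptor network gap was 0.26, fatty acid oxidation 0.20, the respiratory chain -0.0660, stress remodelling 2.26, the unfolded protein response (L3 minus L1) -0.16 against 0.90, and autophagy -0.39. The fibroblast-like matrix list was 1.91 and resident macrophage genes (L3 minus L1) -0.29 against 1.51. In endothelial-like nuclei the sarcomere list (L2 minus L4) was -0.0636 against 0.64, activation genes (L4 minus L1) 1.27 against 1.04, and resident macrophage genes (L3 minus L1) -0.52 against 2.02. In macrophage-like nuclei fatty acid oxidation (L1 minus L2) was -0.28 and the sarcomere list (L1 minus L3) -0.0566 against 2.31. Esrrg was 485, 545, 416 and 455, the L3 to L1 log2 ratios of Spp1 and Timp1 were -0.0432 and -0.14, and against other classes the receptor network was 1.60 and fatty acid oxidation 1.47. Counts below 0 were set to 0 in this setting, so the turned signs of Spp1 and Timp1 are not read as reversed differences.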

Other observations

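Among the tests below, both tests of Esrrg and the values without cluster 8 were chosen only after the result was seen, and the tests of library 2 and of the stress remodelling genes had been set beforehand.

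Interferon genes, which block viral replication, stood at different levels in the libraries, and not in the same order in each class. Relative to all genes and to the 4-library mean, the list lay at -0.18, 0.40, -0.60 and 0.39 log2 in macrophage-like nuclei of libraries 1 to 4, at -0.24, 0.40, -0.36 and 0.08 in fibroblast-like nuclei and at 0.39, 0.09, -0.42 and 0.07 in endothelial-like nuclei. Mx1, an antiviral GTPase, stood at 47.3, 153, 14.2 and 69.9 CPM in macrophage-like nuclei, and Mx2 at 79.5, 66.5, 13.2 and 52.3 CPM in endothelial-like nuclei. Cell cycle genes lay at -1.72, 0.48, 0.96 and 0.36 in fibroblast-like nuclei and at 0.03, -0.04, 0.40 and -0.43 in macrophage-like nuclei. Top2a, a topoisomerase of dividing cells, stood at 16.4, 186, 379 and 205 CPM and Mki67 at 9.80, 125, 295 and 141 CPM in the fibroblast-like class. Vegfa also stood at different levels outside cardiomyocyte-like nuclei, at 657, 1275, 94.1 and 182 CPM in fibroblast-like and 218, 685, 28.3 and 44.7 CPM in endothelial-like nuclei. It was higher in the cardiomyocyte-like nuclei of each library. Free RNA was put at 17.5, 43.7, 44.7 and 38.3% of fibroblast-like and 20.2, 42.3, 58.5 and 43.2% of endothelial-like UMIs. Cardiomyocyte RNA carried over may therefore account for these Vegfa values and was not excluded.

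Esrrg and its coactivator did not keep 1 ratio across classes. In fibroblast-like nuclei Esrrg stood at 130, 29.4, 25.2 and 22.8 CPM and Ppargc1a at 58.1, 21.6, 2.72 and 7.47 CPM, so that Esrrg was the higher of the 2 in all 4 libraries, with overlapping intervals in library 2. Both genes were higher in the cardiomyocyte-like nuclei of each library, and free RNA was put at 17.5, 43.7, 44.7 and 38.3% of fibroblast-like UMIs. Carried-over cardiomyocyte RNA may therefore account for part or all of these fibroblast-like values and was not excluded. In cardiomyocyte-like nuclei Ppargc1a was the higher in libraries 1 and 4, at 622 and 205 CPM against 432 and 174 CPM. The intervals overlapped in library 2, at 321 against 339 CPM, and in library 3, at 162 against 156 CPM. Without cluster 8 the library 3 values of Ppargc1a and Esrrg were again close, at 286 against 293 CPM, from 527 and 540 UMIs. Libraries 3 and 4 resembled one another in all 4 classes, with correlations across genes of 0.973, 0.978, 0.974 and 0.965 in cardiomyocyte-like, fibroblast-like, endothelial-like and macrophage-like nuclei. The other pairs of libraries gave 0.722 to 0.904 in cardiomyocyte-like nuclei. Among unnamed clusters, cluster 0 held 9793 nuclei at a median of 570 UMIs, cluster 9, led by Dipk2b, Shank3 and Erg and scoring highest for endothelial markers with only 1 marker past the bounds, held 1135 at 1391, and cluster 7, led by Acta1, Mb and mitochondrial transcripts, held 761 nuclei of library 3 and 869 of library 4 at a median of 962 UMIs.

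Esrrg stood at 432 CPM in the cardiomyocyte-like nuclei of library 1 and 156 CPM in those of library 3. A gap in depth was argued against as the whole cause, since among nuclei of the same depth class the library 1 value was still 1.99 times (1.84 to 2.17) that of library 3. The ratio was 1.49, 1.69, 2.34 and 4.00 from the shallowest to the deepest class, and 1.46 (1.31 to 1.62) without cluster 8, where the lower bound missed the 1.5 set for the test, so a part for depth stays open. RNA of other cells mixed into the class may account for the gap and was not excluded, since per 1000 UMIs of cardiomyocyte markers Esrrg stood at 10.2, 11.5, 13.9 and 13.2 in libraries 1 to 4, a library 1 to library 3 ratio of 0.73, while the markers took 4.22, 2.94, 1.12 and 1.32% of UMIs. No biological explanation was tested, because the libraries are not tied to the groups, so a true difference in the receptor also stays open.

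In library 2, 80.7% of nuclei had under 1000 UMIs, against 35.9, 9.96 and 17.5% in libraries 1, 3 and 4, and most lay in clusters that no marker set named. Nuclei of several classes read at low depth, with no more mixed RNA than in library 1, were argued against. Their marker UMIs would cluster in some barcodes as in library 1, yet the excess of the dispersion index over 1 in library 2 was 0.0506 of that in library 1. Nuclei among more free RNA, which also lowers the index, cannot be told apart by this test. Free RNA was put at 47.1, 43.7, 42.3 and 57.4% in cardiomyocyte-like, fibroblast-like, endothelial-like and macrophage-like nuclei of library 2, against 27.7, 17.5, 20.2 and 52.3% in library 1. Droplets that hold free RNA and no nucleus could be a candidate explanation. The dispersion index of marker UMIs in library 2 had a median of 1.23 over 5 classes, against 5.45, 2.91 and 3.28 in libraries 1, 3 and 4, which just missed the bound of 1.2 set for free RNA alone, and the question stays open. No biological explanation was tested, since library 2 is not tied to a group.

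Whether nuclei with more stress remodelling transcripts hold fewer transcripts for fuel use was asked inside each library, as a hypothesis. Between the third of cardiomyocyte-like nuclei with most and the third with fewest such UMIs, fatty acid oxidation differed by a median log2 of -0.13, below 0 in 3 of 4 libraries, and the receptor network by -0.0206, below 0 in 2 of 4, which leaves the hypothesis open. Without cluster 8, fatty acid oxidation differed by -0.69, below 0 in 4 of 4 libraries, and the receptor network by -0.63, below 0 in 3 of 4. The sarcomere list then differed by -0.51, against 0.25 over all nuclei, and the respiratory chain by 0.01, so without cluster 8 a lower share of cardiomyocyte RNA in those nuclei may also play a part and was not told apart.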
